A study of Caenorhabditis elegans with 4 samples.

How the data were processed

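Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on wild-type N2 embryos of mixed stages from Caenorhabditis elegans, with a rabbit polyclonal antibody against IMB-1, the nematode importin beta. The series holds 4 samples, which are 2 ChIP replicates and 2 input DNA samples. Per the labels' protocols, embryos were fixed with formaldehyde, chromatin was sheared by sonication, and a portion of each extract was kept as input. The labels number the replicates but do not say whether they came from separate cultures, so the difference between replicates may be in part technical. Peak lists of the 2 ChIP replicates and of the series as a whole were analysed here. Input signal, read coverage and read counts were not analysed here, so no ChIP-to-input value was computed and the sequencing depth behind each list is unknown.

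Reads were aligned with BWA to build ce10, per the submitters' processing notes. The replicate peaks were called with MACS and the series-level peaks with MACS v2, on WormBase WS220, per the file headers and source columns. The aligner and peak caller settings, the control used and the calling threshold are not given in the sources used here. Each list gives a start, an end and a score for every peak, and the score is the authors' own value as deposited, on a scale that the file headers do not name. Scores were therefore used only to rank peaks within a list. In the replicate lists 56 and 42 peaks were tied at the same high score, which was not the highest score of either list. The series-level list names no sample, and the sources used here do not say whether the replicates were pooled to make it. All of its value columns were mapped, and its peaks carry no replicate error.

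A peak was counted as shared when at least 1 bp of it was covered by a peak of the other list. The chance level came from 100000 random circular shifts, in which all peaks of a chromosome were moved together by 1 random distance. The resulting p is a one-sided permutation p, of which the smallest possible value is 1e-05. Shared replicate peaks were paired one to one by the largest overlap, and the Spearman correlation of their scores was tested by 100000 permutations, two-sided. Clustering was the share of peaks with another peak of the same list within 5 kb, tested one-sided against 10000 uniform random placements on the same chromosome, with a smallest possible p of 0.0001. Median widths were compared by 100000 permutations, two-sided. Peak numbers per chromosome, on X and in the outer parts of the autosomes (66.7% of their length, taken equally from both ends) were compared with the share of length by two-sided exact binomial tests, with Benjamini-Hochberg adjustment over the 6 chromosomes of a list. Intervals are exact Clopper-Pearson 95% intervals. The binomial tests, Fisher's exact tests, the permutation test of widths and all intervals treat peaks as independent and cover counting error only. Many peaks stood in groups, and many sites were in both replicate lists. The shifts and placements likewise take all positions of a chromosome as equally able to hold a peak. None of these p-values measures the spread between replicates, for which values of both replicates are given.

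The lengths of chromosomes were taken as the largest peak end in any list, since the file headers give none. The gene table at hand belongs to another assembly, WBcel235, and coordinates were not carried between builds. Planned tests of peaks at transcription start sites and of gene classes were therefore not run, and peaks are named by WS220 coordinates, counted from 1, without genes. Peaks named in the text follow a rule set before the data were examined, as were all comparisons and alternatives unless stated otherwise. The rule took the 10 series-level peaks of highest score that touched both replicates, the 5 widest such peaks, and the 5 windows of 100 kb with the most series-level peaks. The counts at left chromosome ends, on the mitochondrial genome and among the 100 highest-scoring peaks were not planned. Chosen after the data were seen were the runs of peaks, defined as 10 or more peaks with gaps of at most 5 kb, the grouping of peaks by score, results without these runs, the X share of shared and unshared peaks, the Fisher's exact tests between replicates and the exact McNemar test of series-level peaks touching 1 replicate alone. Results without runs left out of every list each peak that touched a run of any list. This kept 1708 series-level, 1317 replicate 1 and 1599 replicate 2 peaks.

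The alternatives were a reciprocal overlap of 50%, peak middles within 200 bp, the higher-scoring 50% and 25% of each list, lists of equal length, uniform placement, merging within 5 kb, covered bases in place of peaks, other arm and gap limits, and 1 replicate at a time. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The tests were tried on simulated lists with the real list sizes, widths and chromosome lengths. Of 100 pairs of unrelated lists, 2 gave an overlap p under 0.05. Of 100 uniform lists of the size of replicate 2, 5 passed the clustering test and 4 the test of X. A planted overlap of 30% between lists of the replicates' sizes was recovered as 31.0%, and a planted X-to-autosome ratio of 1.5 in lists of the size of replicate 2 as 1.49. Simulated peaks were placed independently of each other, whereas the real peaks stood in groups. The simulations therefore do not show how often the tests pass by chance for clustered peaks.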

Results

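Genomic sites associated with IMB-1 were sought by ChIP-seq in mixed-stage N2 embryos, N2 being the standard wild-type laboratory strain of C. elegans. IMB-1 is the importin beta of this nematode, a transport receptor that carries proteins through nuclear pores. Peaks were called in each of 2 ChIP replicates, and a further list was deposited for the series as a whole. Replicate 1 had 1753 peaks, replicate 2 had 1620 and the series-level list had 2008. The peaks were short and covered a small part of the genome. The median width was 234 bp (quartiles 158 and 430 bp) in replicate 1, 301 bp (190 and 471 bp) in replicate 2 and 302 bp (196 and 514 bp) in the series-level list. Nuclear peaks covered 0.803% of the genome in replicate 1, 0.764% in replicate 2 and 1.08% in the series-level list. The median width was 67 bp larger in replicate 2 than in replicate 1 (permutation test, p = 1e-05, the smallest it can give). Among the higher-scoring 50% of each list the difference was 26 bp (permutation p = 0.0623). Both p-values take peaks as independent and do not measure the spread between replicates. The lists give no read counts, so the depth behind each peak is unknown.

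The first comparison asked which called peaks were found in both replicates. The strongest peaks were largely the same and the weaker ones largely differed. Input was not analysed here, so agreement between replicates does not by itself show that IMB-1 was bound at a shared peak. Of the 100 peaks of highest score in replicate 1, 92 touched a peak of replicate 2, and of the 100 highest in replicate 2, 89 touched a peak of replicate 1. Over whole lists, 609 of 1753 replicate 1 peaks (34.7%, 95% interval 32.5 to 37.0%) touched a replicate 2 peak, and 595 of 1620 replicate 2 peaks (36.7%, 34.4 to 39.1%) touched a replicate 1 peak. Circular shifts gave 1.42% and 1.39%, so the overlaps were 24.4 and 26.4 times the chance level (permutation p = 1e-05 for both, the smallest the shifts can give).

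Sharing rose with the score in both directions. In replicate 1, 13.2% (95% interval 10.2 to 16.7%) of the 25% of peaks with the lowest scores were shared, against 71.9% (67.5 to 76.1%) of the 25% with the highest scores. In replicate 2 the corresponding shares were 17.5% (14.0 to 21.6%) and 61.2% (56.3 to 66.0%). The 561 one-to-one pairs of shared peaks had a Spearman correlation of 0.58 between their scores (permutation p = 1e-05) and of 0.73 between their widths (permutation p = 1e-05). These correlations are across peaks, which are not independent replicates.

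**Figure D1:**
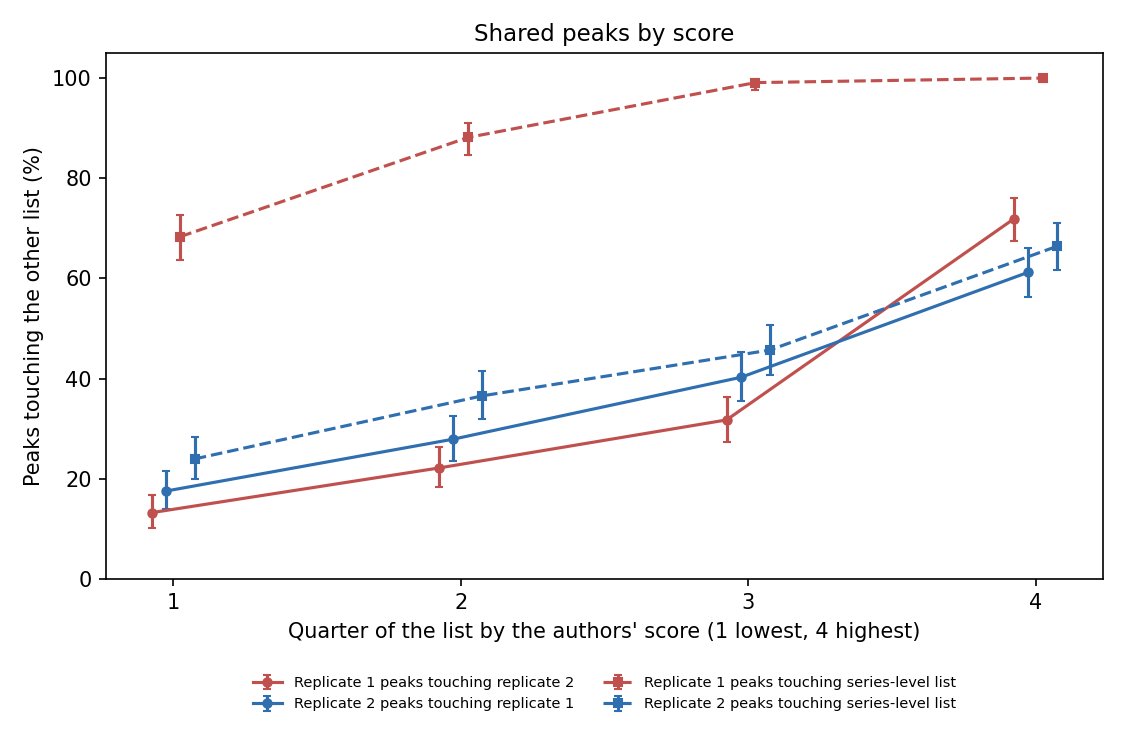
The vertical axis gives the percentage of peaks of one list that touch a peak of another, with exact 95% binomial intervals, and the horizontal axis gives 4 equal groups of the first list by the authors' score, from lowest to highest. Replicate 1 peaks touching replicate 2 go from 13.2% to 71.9%, while replicate 1 peaks touching the series-level list go from 68.3% to 100%.

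The 10 highest-scoring series-level peaks that touched both replicates were spread over all 6 nuclear chromosomes. The highest-scoring shared peak of the series-level list was on chromosome I at 9382614 to 9383410 (797 bp), followed by 1 on chromosome III at 10224453 to 10225901 (1449 bp). The third and the fourth were neighbouring peaks on chromosome V at 17119881 to 17126659 (6779 bp) and 17128104 to 17132162 (4059 bp), in a part of the chromosome that holds, as background, a tandem array of ribosomal RNA genes. Next came chromosome II at 4129911 to 4130610, X at 15807143 to 15811219 and IV at 2828400 to 2830646. Chromosome I at 15060179 to 15071415 was eighth by score and, at 11237 bp, the widest of all shared peaks. It lies at the right end of the chromosome, where as background the large ribosomal DNA repeats are found. The remaining peaks of the first 10 were on X at 11643521 to 11644262 and on IV at 11070801 to 11075939.

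The other widest shared peaks were on X at 10360912 to 10369178 (8267 bp), on V at 7916790 to 7925053 (8264 bp), on I at 4540315 to 4547818 (7504 bp) and on V at 10605579 to 10612498 (6920 bp). Each replicate covered 96.1 to 99.4% of each of the 5 widest shared peaks. The widest of them, on I, was covered to 98.8% by replicate 1 and to 99.0% by replicate 2. The peak at 4540315 on I was a single peak in the series-level list, but 3 peaks in replicate 1 and 5 in replicate 2. Among the 10 highest-scoring peaks, the coverage by replicate 2 was lowest for the peak on III at 10224453, at 71.8%.

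The second comparison asked how the series-level list relates to the replicates. It followed replicate 1 more closely than replicate 2. Of its 2008 peaks, 1217 (60.6%, 95% interval 58.4 to 62.8%) touched replicate 1 and 648 (32.3%, 30.2 to 34.4%) touched replicate 2, against 1.46% and 1.54% by circular shifts (permutation p = 1e-05 for both). The list was deposited for this same series, so an overlap above chance was bound to appear and these p-values add no support. Both replicates were touched by 534 peaks (26.6%), replicate 1 alone by 683 (34.0%), replicate 2 alone by 114 (5.68%) and neither by 677 (33.7%). The counts of 683 and 114 differed (exact McNemar test, two-sided, p = 1.35e-99). This p takes peaks as independent, although many of them stood in groups, so it overstates the evidence. The peaks touching both were the widest, with a median of 525 bp, and those touching neither the narrowest, with 196 bp. Seen from the replicates, 88.9% of replicate 1 peaks and 43.1% of replicate 2 peaks touched the series-level list. All 438 peaks in the highest-scoring 25% of replicate 1 did so, against 269 of 405 (66.4%, 61.6 to 71.0%) in replicate 2. Among the 100 peaks of highest score, 100 of replicate 1 and 94 of replicate 2 touched it.

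The third comparison concerned the chromosomes. Replicate 2 had more peaks on X than its length predicts, and replicate 1 did not pass that test. On X, replicate 2 had 20.0 peaks per Mb against 15.3 on the autosomes, a ratio of 1.31 (95% interval 1.16 to 1.47, exact binomial p = 1.44e-05). The ratio was 0.92 (0.81 to 1.04, exact p = 0.199) in replicate 1 and 1.00 (0.89 to 1.12, exact p = 0.953) in the series-level list. The share of peaks on X was 21.9% in replicate 2 and 16.5% in replicate 1 (Fisher's exact test, two-sided, p = 6.53e-05). Fisher's tests take peaks as independent, although many stood in groups and many sites were in both lists. Their p-values do not measure the spread between replicates. With peaks within 5 kb merged the shares were 23.3% and 19.9% (Fisher's exact p = 0.0684), and without runs of closely spaced peaks they differed by 2.88 percentage points (Fisher's exact p = 0.0598). With autosomal runs alone left out they differed by 0.82 points (Fisher's exact p = 0.623). Without any of the runs the ratio of replicate 1 turned to 1.10 (exact p = 0.17), not significant in either direction, and that of replicate 2 was 1.32 (exact p = 9.35e-06). Peaks shared between the replicates had ratios above 1, at p-values that take peaks as independent although many stood in groups. The X-to-autosome ratio was 1.26 (exact p = 0.0194) for the 609 shared peaks of replicate 1 and 1.25 (exact p = 0.0275) for the 595 of replicate 2. These are the same places counted from either list, so the likeness of the ratios is no separate support. Series-level peaks touching both replicates had a ratio of 1.24, with an interval of 0.99 to 1.53 that includes 1. Peaks of replicate 1 outside replicate 2 had a ratio of 0.75 (exact p = 0.000641), which was 0.96 (exact p = 0.697) without the runs, and peaks of replicate 2 outside replicate 1 had a ratio of 1.34 (exact p = 0.000137). These ratios were not tested against each other.

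Among the autosomes, chromosomes III and IV were the densest and V the sparsest in the series-level list. Its density was 23.1 peaks per Mb on III (exact binomial test, adjusted p = 0.0141), 23.4 on IV (adjusted p = 0.00382) and 17.3 on V (adjusted p = 0.00624), against 20.0 over the nuclear genome. Replicate 1 had 1.29 times its mean density on III (exact test, adjusted p = 1.16e-05) and 1.22 times on IV (adjusted p = 0.00011), with lower densities on I (0.80 times, adjusted p = 0.000691) and V (0.84 times, adjusted p = 0.00108). In replicate 2 chromosome V was low at 0.80 times the mean (exact test, adjusted p = 9.43e-05), and III and IV were both at 1.00 times. The difference between the replicates was not tested for single autosomes. The excess on III rested on runs of closely spaced peaks. Without these runs, replicate 1 had 0.83 times its mean density on III (exact test, adjusted p = 0.0488) and still 1.29 times on IV (adjusted p = 1.36e-05), while I at 0.96 times (adjusted p = 0.563) and V at 0.91 times (adjusted p = 0.127) no longer passed the test with fewer peaks. In the series-level list without the runs, IV passed at 1.18 times the mean density (exact test, adjusted p = 0.00381). Chromosome III turned from 1.15 to 0.87 times and V went from 0.87 to 0.90 times, and neither passed the exact test (adjusted p = 0.0794 for both). In the series-level list, 0 of 6 chromosomes passed the adjusted exact binomial test with peaks merged within 5 kb (2 at an unadjusted p under 0.05), and 0 with peaks touching both replicates (1 unadjusted), against 3 with all peaks.

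In the series-level list and in replicate 1, autosomal peaks were over-represented in the outer parts of the chromosomes, which in C. elegans are rich in repeats, relative to the gene-dense centres. In the series-level list 73.4% of 1650 autosomal peaks (95% interval 71.2 to 75.5%) were in the outer parts, which make up 66.7% of the length (exact binomial p = 3.96e-09). The share was 72.1% in replicate 1 (69.8 to 74.4%, exact p = 7.88e-06) and 68.5% in replicate 2 (65.9 to 71.1%, exact p = 0.161). The replicates differed by 3.59 percentage points (Fisher's exact p = 0.0434). Without runs of closely spaced peaks the shares were 77.7% and 68.4%, a difference of 9.25 points (Fisher's exact p = 6.72e-07). Both Fisher's tests take peaks as independent, although many stood in groups and many sites were in both lists. Neither p measures the spread between replicates. On X, the outer parts held 77.2% of the peaks in replicate 1 (exact p = 0.000105) and 74.4% in replicate 2 (exact p = 0.00192). Among the higher-scoring 50% of the series-level list the autosomal share was 68.6% (exact p = 0.261).

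**Figure D2:**
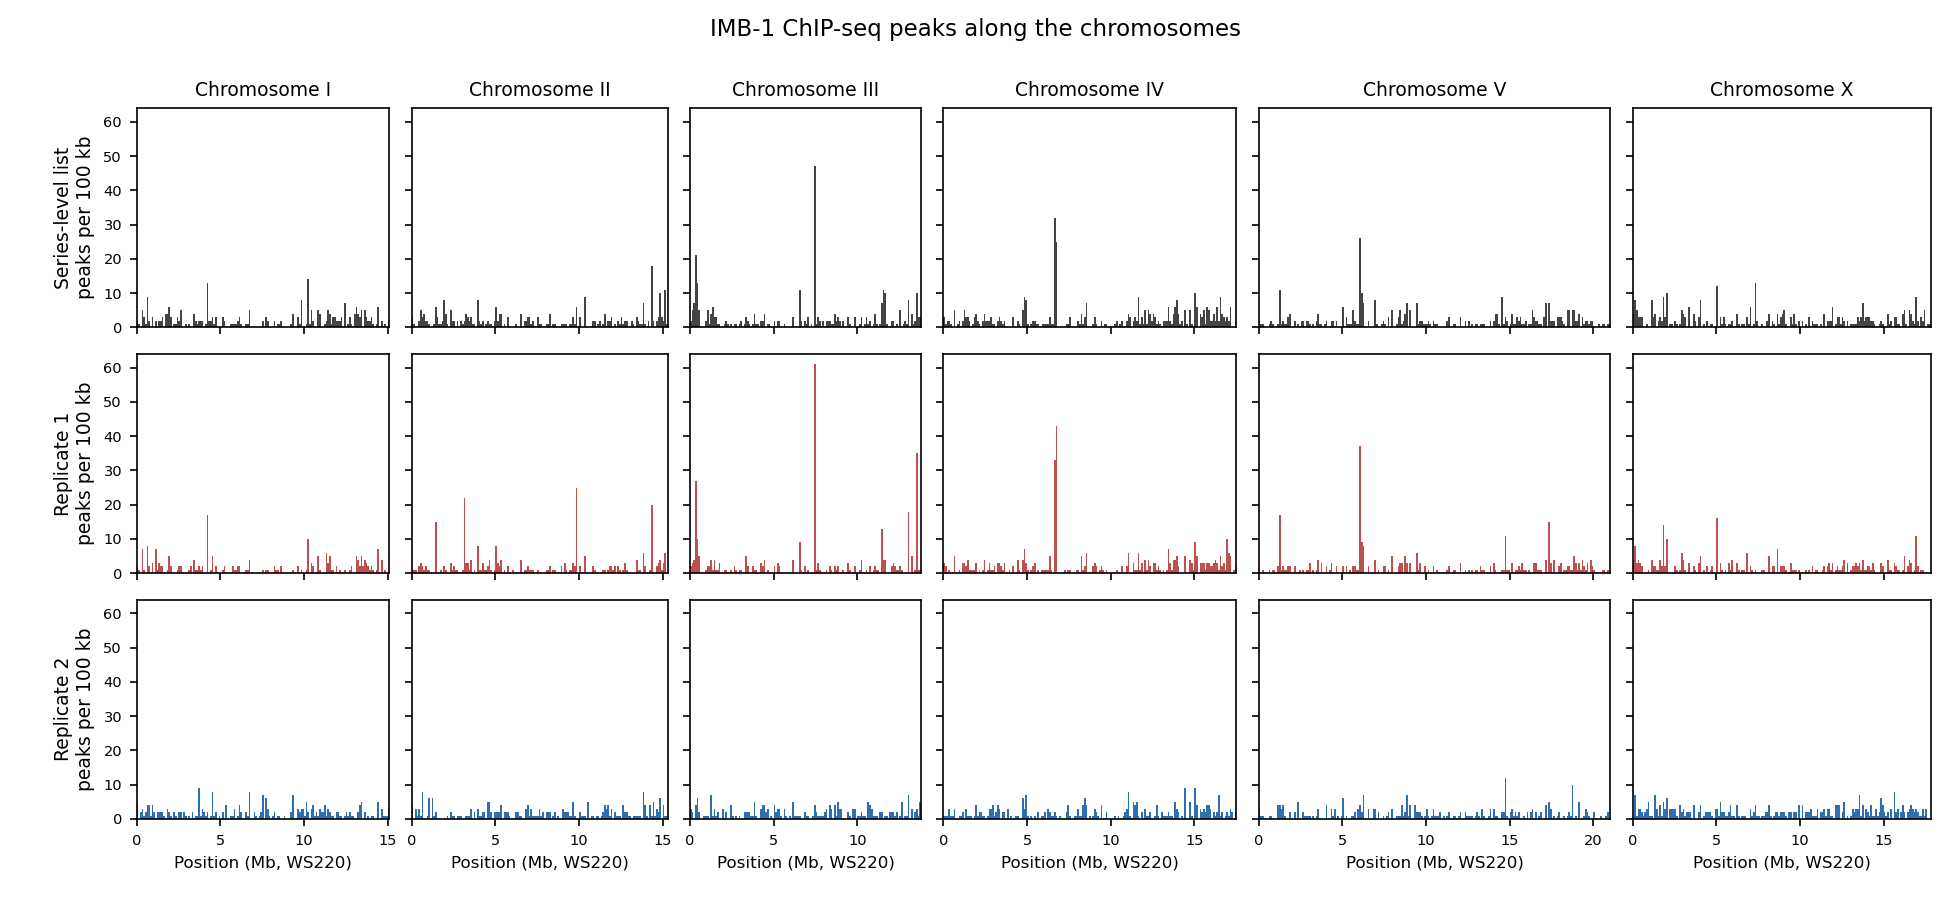
Each bar is the number of peaks whose middle lies in a window of 100 kb, plotted against WS220 position in Mb for the 6 nuclear chromosomes, with 1 row for each list. Replicate 1 reaches 61 peaks in a window on chromosome III, the series-level list 47 in the same window, and replicate 2 no more than 12 in any window.

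The fourth comparison asked whether peaks stood in groups. They did in all 3 lists. In replicate 1, 65.9% of peaks had another peak within 5 kb, against 17.8% by uniform placement (permutation p = 0.0001, the smallest it can give). The shares were 41.6% against 16.4% in replicate 2 and 61.2% against 20.0% in the series-level list (permutation p = 0.0001 for both). The difference between the replicates in this share was not tested. The 5 densest windows of the series-level list had 27 to 61 peaks in replicate 1 and 1 to 4 in replicate 2. On III from 7400001 to 7500000 there were 47 series-level, 61 replicate 1 and 4 replicate 2 peaks. On IV from 6600001 to 6700000 there were 32, 33 and 2, and in the adjoining window from 6700001 there were 25, 43 and 1. On V from 6000001 to 6100000 there were 26, 37 and 4, and on III from 300001 to 400000 there were 21, 27 and 4.

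These windows contained runs of peaks with narrow limits. Runs of peaks were looked at after the windows had been seen. Replicate 1 had 17 runs of 10 or more peaks with gaps of at most 5 kb, holding 406 peaks (23.2% of the list). The series-level list had 14 such runs with 254 peaks, and replicate 2 had 0. The longest run in replicate 1 extended from 7405335 to 7452720 on III (47.4 kb, 60 peaks), with 4 replicate 2 peaks inside it, and the series-level list had 45 peaks from 7405344 to 7452622. On IV, 65 replicate 1 peaks lay between 6684472 and 6731167 and no replicate 2 peak did. On V, 37 replicate 1 peaks and 4 replicate 2 peaks lay between 6070794 and 6094516.

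**Figure D3:**
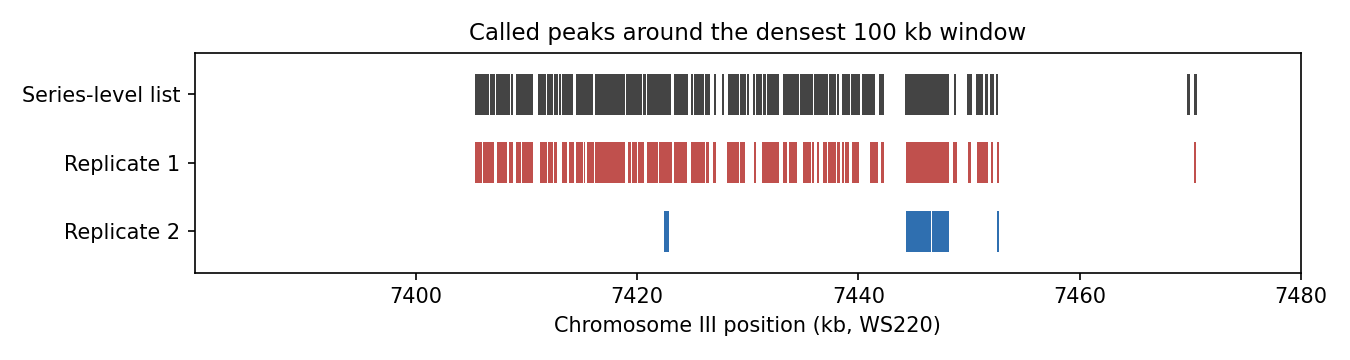
Called peaks between 7380001 and 7480000 on chromosome III, drawn to scale as filled bars against WS220 position in kb, with 1 row for each list. The series-level list and replicate 1 have 47 and 61 peaks here, most of them in 1 continuous run, and replicate 2 has 4.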

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

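Leaving out the runs of peaks and the alternatives for peak width were chosen after the data were seen, and all others before. Of 79 alternatives over 13 results, 68 kept the direction and the side of the threshold, or for counts and untested values stayed within the set limits. These include every alternative for the overlaps, the score ranks and the clustering, all at the smallest p the tests can give. For the overlaps of the series-level list that outcome was bound to appear, since the list belongs to the same series. The share of series-level peaks touching at least 1 replicate was 66.3%. It was 32.3% without replicate 1 and 60.6% without replicate 2. The other alternatives gave 43.8% with a reciprocal overlap of 50% to 73.9% with the highest-scoring 25% of each list. Replicate 1 peaks touching replicate 2 ranged from 23.3% with a reciprocal overlap of 50% to 45.3% with both lists limited to their highest-scoring 25%, and a reciprocal overlap lowered the series-level overlap with replicate 1 to 37.8%. The series-level list could not be made again from 1 replicate, so leaving out a replicate means using the list of the other in its place for the results on X, chromosomes and arms. The X-to-autosome ratio was 1.00 in the series-level list, 0.92 without replicate 2, a reversal without significance, and 1.31 without replicate 1. It became significant at 1.24 among peaks touching both replicates, with an exact binomial p of 0.0471 and an interval that includes 1, and at 1.19 without the autosomal runs (exact p = 0.00346), which removes peaks from the autosomes only. The number of chromosomes past the threshold fell from 3 to 0 with peaks merged within 5 kb, 0 with peaks touching both replicates and 1 without the runs. It was 2 in replicate 2 alone (V and X) and 4 in replicate 1 alone (I, III, IV and V), and merged and shared peaks are fewer than all peaks. The arm share, 73.4%, was 76.8% without the runs and 74.0% with merged peaks. It lost significance at 68.6% in the higher-scoring 50% of the list and at 68.5% without replicate 1, and was 72.1% without replicate 2. By covered bases it was 69.6%. The width difference fell to 26 bp in the higher-scoring 50%, where it was not significant. The cause was not tested for these changes except where stated. Density by covered bases has no count test and gave no value for the number of chromosomes. The planned tests at gene starts and of gene classes, with their alternatives, were not run, because the gene table is of another build. No paired analysis was possible because input peaks or signal were not analysed here, so ChIP and input replicates of the same number were never compared. The read depth of each list is unknown, so a site missing from 1 replicate was not called there, which does not show that IMB-1 was absent.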

Other observations

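Peaks were also called at the left chromosome ends and on the mitochondrial genome. These counts were not among the planned comparisons. In each of the 3 lists, all 6 nuclear chromosomes had a peak within the first 1 kb of their left end, where 0.12 chromosomes would be expected for the series-level list, 0.105 for replicate 1 and 0.0967 for replicate 2 with uniform placement. Right ends could not be examined in this way, since chromosome lengths were themselves taken from the largest peak ends. The counts therefore do not show that such peaks are particular to left ends. The series-level list had 3 peaks on the mitochondrial genome, from 196 to 10461, 10772 to 12899 and 13051 to 13227, which together covered 12571 bp of the 13227 bp up to the last peak base. Both replicate lists had 0 mitochondrial peaks. The sources used here do not say whether mitochondrial reads were kept for the replicate lists.

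The tests of the runs, of weak peaks on X and of the series-level list were chosen after the result they concern was seen. The test of X without the runs was set before its result was seen. No biological explanation was tested, since both replicates belong to the same group.

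Runs of closely spaced peaks were found in replicate 1 and the series-level list. Peaks touching replicate 2 numbered 18 of 406 in the runs, 0.102 times the number expected from peaks of like score outside them, but this in part restates the dense windows that drew attention to the runs. In the 12 runs outside the 5 densest windows, 11 of 210 peaks touched replicate 2, 0.107 times the expected number (95% interval 0.054 to 0.187, taking peaks as independent), which argues against a lower overall recovery of replicate 1 peaks in replicate 2 as the only source. These 12 runs were also defined in replicate 1 after the data were seen. Peaks of the same run are not independent, so the interval is too narrow. Peaks covered 67.3% of the bases of the median replicate 1 run (21.0 to 88.1% over 17 runs), which is consistent with continuous signal that the peak caller divided into short peaks. Candidate explanations that stay open and were not tested are extra copies of these segments in the material of replicate 1, and true binding along long regions in that sample only.

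The share of peaks on X was 5.43 percentage points higher in replicate 2 than in replicate 1. Weak peaks of replicate 2 are argued against as the source, since the difference was 6.13 points in the higher-scoring 50% of each list (Fisher's exact p = 0.00202). This p and those below take peaks as independent and do not measure the spread between replicates. Autosomal runs in replicate 1 cannot be told apart from a difference on X itself. Without any runs, those on X included, the difference was 2.88 points (Fisher's exact p = 0.0598), over 50% of that for all peaks but not significant. Without the autosomal runs alone, tested after this was seen, it was 0.82 points (Fisher's exact p = 0.623), but this keeps the runs on X that replicate 1 has and replicate 2 lacks, so the runs may account for part or all of the difference.

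The series-level list resembled replicate 1. The overlaps themselves leave no room for a rule that keeps only peaks found in both replicates, since 32.3% of its peaks touched replicate 2 and 26.6% touched both, and this is no separate test. It touched 24.0% of the lowest-scoring 25% of replicate 2 and 66.4% of the highest-scoring 25% (95% interval 61.6 to 71.0%). In replicate 1 these shares were 68.3% and 100%. A loss of weak replicate 2 peaks only is thus argued against, since peaks of its highest-scoring 25% were missing too. The list did touch 94 of the 100 strongest replicate 2 peaks. Whether strength on a scale common to both replicates decided what was kept stays open, since scores were ranked within lists. A further candidate explanation is that the list was called on joined reads in which replicate 1 weighed more, which was not tested because read numbers are unknown.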
